A study of Mus musculus with 6 samples.

How the data were processed

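Nrf1 ChIP and input DNA were each sequenced in 3 replicates from fibroblasts of wild-type mouse embryos treated with MG132, and every sample was placed in its group by its title. The labels name an antibody against TCF11, another name of Nrf1, and libraries made with a low-input multiplex kit. Per the submitters' processing notes, the tools were BWA 0.6.2-r126, SAMtools 0.1.18, MACS2 2.0.10 and bedtools 2.17.0 and the build was mm9; the notes used here give no role, order or parameters for them. The authors deposited 1 peak list per ChIP library, so replicates were not pooled before calling. Each list has 5 columns without a header: chromosome, start, end, peak name and a score. The deposited score is a −log10 value of a p or q. Which of the pair it is was not given in the sources used here; its lowest values were 1.31, 1.30 and 1.33 in replicates 1, 2 and 3, where −log10 of 0.05 is 1.30. The score depends on depth, so it was used only to describe, rank or filter peaks within a list. The authors' filters beyond this, including any removal of repeated or anomalous regions, were not given in the sources used here, and peaks on chromosome Y and in wide stretches were kept as deposited. How the authors used the input libraries in the calling was not given in the sources used here, and the inputs gave no values of their own here.

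All tests were written for peak lists, and their design was fixed before the data were examined, except where the text says otherwise. Peaks of the 3 lists (36730 in all) that overlapped by at least 1 bp were merged into union regions, and a region counted for a replicate if it held at least 1 of its peaks. Overlap was compared with 1000 random placements of each list, in which every peak kept its width and chromosome and fell between the first and last peak of that chromosome; for pairs, the shorter list was placed and the longer one kept. The placement leaves out mappability and open chromatin, which also bring peaks of separate libraries together. Shares have exact Clopper-Pearson 95% intervals. Agreement of order was Spearman's rho over regions with a peak in both lists, with the highest score of each. Score deciles were cut from percentile ranks, with ties kept together. Peak density was the number of peaks per Mb between the first and last peak of a chromosome, divided by the median of the 19 autosomes in that list. The named regions were, by a rule fixed in advance, the 10 with the best mean percentile rank of the score among regions present in all 3 lists. The replicates are separate samplings of one kind of cell, per the labels, and no untreated sample or sample lacking Nrf1 is among those used here.

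Gene-based comparisons were planned with 15 gene lists (395 entries, among them proteasome subunits, degradation at the endoplasmic reticulum, antioxidant genes and controls), distances to transcription start sites and 11 sequence motifs. They were not made. The gene table used here is of GRCm38, on 9 of 21 chromosomes peaks lie past the end of its last gene, and coordinates were not converted between builds. Regions are therefore given by mm9 position only.

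The overlap step was tested on simulated data before use, with all 36730 peaks placed at random and sites planted in replicates 1 and 2. Of 1000 planted sites it returned 101% and of 5000 it returned 99.1%, after subtracting random overlap. Planted peaks started within 50 bp of their partner, so their overlap was nearly fixed by construction. These figures check the counting only. Alternatives were the stronger 50% of each list and the 1492 strongest peaks of each list, which is the whole of replicate 3. Others were overlap by at least 50% of both lengths, removal of the widest 1% of peaks, and leaving out each replicate. Added after seeing the data were placement within 50 kb of each peak's own position, removal of chromosome Y and removal of chromosomes 6 and 15. Alternatives used 100 placements, or 20 for the 50% overlap. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.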

Results

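Chromatin bound by Nrf1 was profiled by immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic fibroblasts. Nrf1 here is the product of Nfe2l1, a transcription factor of the cap'n'collar family that is held at the endoplasmic reticulum membrane and is known to drive proteasome subunit genes when the proteasome is blocked. It is not nuclear respiratory factor 1, which shares the abbreviation. The fibroblasts came from wild-type embryos, had been immortalised by the large T antigen of SV40, and received MG132, a proteasome inhibitor, at 10 μM for 6 h. The 6 libraries form 2 groups, with 3 replicates of Nrf1 ChIP and 3 of input DNA, from separate samplings of the cells. All 6 were treated, so the contrast in the design is ChIP against input. The files used here hold 1 peak list for each ChIP library, and how the inputs entered the peak calling was not given in the sources used here. The deposited lists held 23187 peaks for ChIP replicate 1, 12051 for replicate 2 and 1492 for replicate 3. Replicate 1 thus had 15.5 times and replicate 2 had 8.08 times as many peaks as replicate 3. Read depths are unknown, since peak lists carry no totals.

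The first question was which sites were found again in an independent sampling. Peaks of the Nrf1 ChIP recurred at the same places. Of 27511 union regions, 8025 (29.2%) held a peak in at least 2 replicates and 1143 (4.15%) in all 3. Random placement of each list on its own chromosomes gave a median of 106 regions in at least 2 replicates (highest 138 of 1000 placements), so the observed number was 75.7-fold higher (one-sided permutation p = 0.001, the smallest that 1000 placements can give). With placement within 50 kb of each peak's own position the excess was 29.8-fold. Neither placement takes in mappability or open chromatin, so the excess alone does not tell Nrf1 binding from these. For all 3 replicates random placement gave at most 4 regions. Most of the regions in at least 2 replicates (6829) were those of replicates 1 and 2 without replicate 3. Without replicate 1 the number shared by the other lists was 1160, and without replicate 2 it was 1183, against 7972 without replicate 3.

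**Figure D1:**
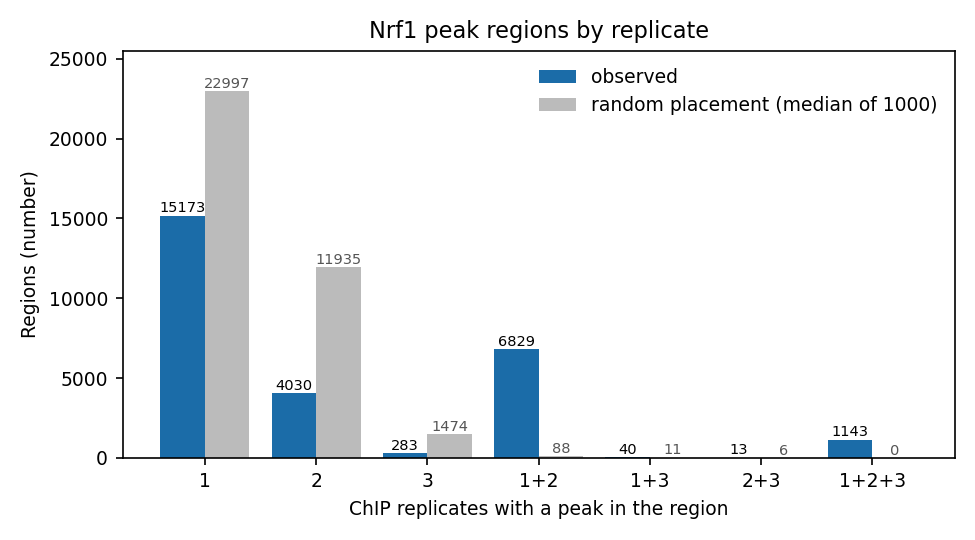
Number of union regions (vertical axis) by the ChIP replicates that held a peak there (horizontal axis). Blue bars are observed numbers and grey bars the median of 1000 random placements; the 1143 regions in all 3 replicates stand against 0 by placement.

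Pair by pair, most peaks of the shorter list were met in the longer one. Of the replicate 2 peaks, 66.5% (8008 of 12051, exact 95% interval 65.6 to 67.3%) overlapped a replicate 1 peak by at least 1 bp, against 0.73% by random placement. Of the replicate 3 peaks, 80.1% (1195 of 1492, interval 78.0 to 82.1%) overlapped replicate 1, against 0.737%, and 78.3% (1168 of 1492, interval 76.1 to 80.4%) overlapped replicate 2, against 0.402%. With the 1492 strongest peaks of each list, the share of replicate 3 peaks met was 57.0% in replicate 1 and 55.7% in replicate 2. Each of the 3 full-list shares exceeded all 1000 placements (one-sided permutation p = 0.001). With placement within 50 kb of each peak's own position the random shares were higher. They were 1.87% for replicate 2 in replicate 1, 3.18% for replicate 3 in replicate 1 and 2.48% for replicate 3 in replicate 2. These intervals cover counting error only. Centres of overlapping peaks lay close together where each list held 1 peak in the region. The median distance between them was 32 bp for replicates 1 and 2, 33 bp for replicates 1 and 3 and 22 bp for replicates 2 and 3. In the same order, 90.2%, 88.4% and 94.5% lay within 100 bp. The need to overlap itself limits these distances.

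Most of the strongest sites of one sampling were strong in the others. Of the 100 strongest peaks of replicate 1, 100 lay in the strongest decile of replicate 2 and 88 in that of replicate 3. Of the 103 strongest of replicate 2, with ties, the strongest decile of replicate 1 held 103 and that of replicate 3 held 86. Only 100 of these 103 were met in replicate 3 at any rank. Of the 100 strongest of replicate 3, 98 lay in the strongest decile of replicate 1 and 96 in that of replicate 2. At any rank, 100 of them were met in replicate 1 but only 96 in replicate 2. All these counts were added after the values were seen. The 10 highest-ranked regions present in every list lay on 6 chromosomes and were 760 to 1287 bp wide (mm9 coordinates, counted from 1). The first was on chromosome 19 at 41529308 to 41530107, ranked 2, 2 and 1 by the authors' score in replicates 1, 2 and 3. The second, on chromosome 2 at 179905736 to 179906828, ranked 1, 1 and 2. The third lay on chromosome 19 at 4045758 to 4046573, with ranks 6, 5 and 4, and the fourth on chromosome 9 at 119550730 to 119551793, with ranks 3, 3 and 5. A region on chromosome 2 at 27595427 to 27596360 ranked 16 in replicate 1 and 6 in both other lists, and one on chromosome 1 at 182939638 to 182940438 ranked 5, 4 and 7. The remaining 4 were on chromosome 11 at 98543640 to 98544399, on chromosome 1 at 87960763 to 87961949, on chromosome 10 at 82321448 to 82322267 and on chromosome 11 at 97564217 to 97565503. Their high ranks follow from the rule that chose them. Of the 10, 5 were among the 10 strongest peaks of each list. None ranked below 16 in replicate 1, 28 in replicate 2 or 12 in replicate 3, and the lowest mean percentile rank was 99.7 ± 0.39 (SD, n = 3). The lists differ in length, so the ranks order sites within a list and show no change between lists. The genes at these positions were not analysed here, because the gene table used belongs to another genome build.

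**Figure D2:**
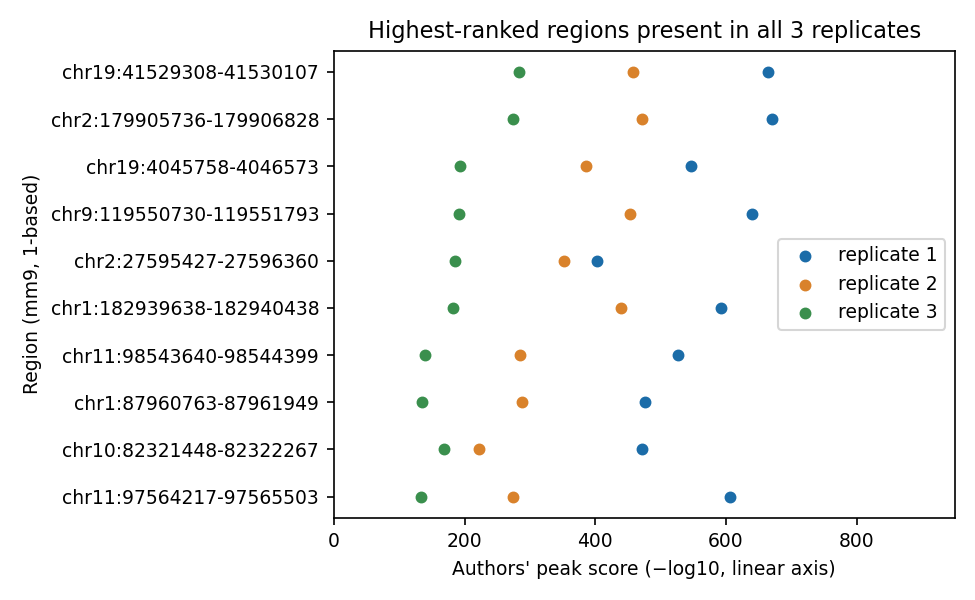
Authors' peak score (horizontal axis, −log10 scale values on a linear axis) of the 10 highest-ranked regions present in all 3 lists (vertical axis, mm9 positions). Points are the 3 ChIP replicates; scores ran from 403 to 670 in replicate 1, from 222 to 472 in replicate 2 and from 134 to 284 in replicate 3.

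Weaker sites were found again less often. Of the strongest decile of replicate 1 peaks, 99.0% (2294 of 2317, exact 95% interval 98.5 to 99.4%) were met in replicate 2 and 41.5% (961 of 2317, interval 39.5 to 43.5%) in replicate 3. In the ninth score decile the shares were 81.8% and 4.58%, in the fifth 16.4% and 0.431%, and in the weakest 2.86% and 0.42%. The order of the shared sites was alike in each pair: across regions, which are not independent replicates, Spearman's rho of the authors' scores was 0.77 for replicates 1 and 2 (7972 regions), 0.75 for replicates 1 and 3 (1183 regions) and 0.76 for replicates 2 and 3 (1156 regions). Peaks found in 1 list alone were weaker and narrower than shared ones in each replicate. Their median width was 294 against 441 bp in replicate 1, 249 against 315 bp in replicate 2 and 222 against 262 bp in replicate 3, and their median score was 5.90 against 25.7, 3.55 against 13.7 and 3.02 against 11.8.

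**Figure D3:**
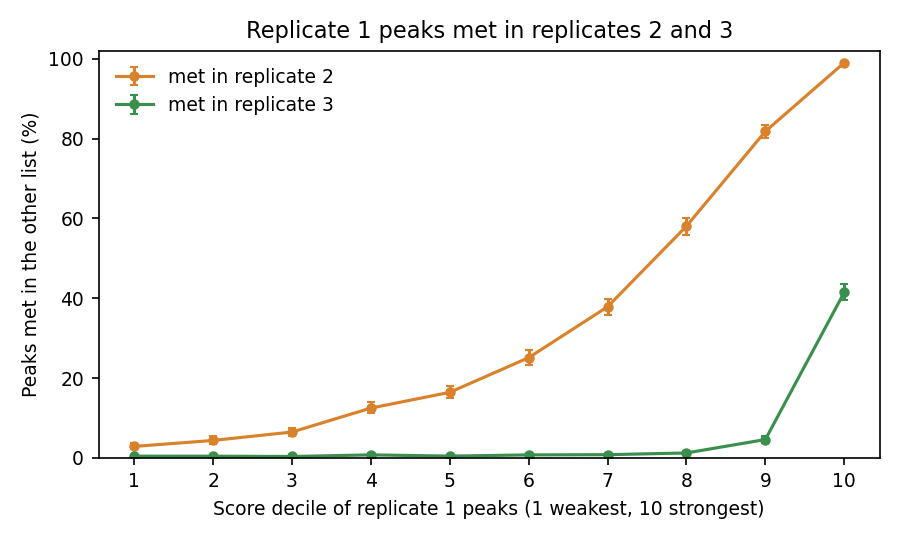
Share of replicate 1 peaks met in replicate 2 or replicate 3 (vertical axis, %) by score decile of replicate 1 (horizontal axis, 1 weakest). Bars are exact 95% binomial intervals; the strongest decile reached 99.0% in replicate 2 and 41.5% in replicate 3.

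Chromosomes 6 and 15 stood apart in peak density by more than the spread between replicates; this and the following comparison were chosen after the values were seen. Chromosome 6 held 1.96 ± 0.15 and chromosome 15 held 1.90 ± 0.10 times the peaks per Mb of the median autosome (SD, n = 3), and each of their replicate values (lowest 1.80) lay above each value of the other autosomes (highest 1.48, chromosome 19). Chromosomes 19 (1.46 ± 0.03) and 11 (1.36 ± 0.10) followed, while chromosomes 4 (0.59 ± 0.04) and 14 (0.52 ± 0.08) were sparse. Chromosome X held 0.27 ± 0.08 times the autosomal median. The excess on chromosomes 6 and 15 was larger among weak and unshared peaks. These chromosomes together held 22.5%, 26.2% and 25.6% of the weaker 50% of replicates 1, 2 and 3, against 13.3%, 13.5% and 8.67% of the strongest decile. They held 19.9%, 32.6% and 48.8% of the peaks found in replicate 1, 2 or 3 alone, against 13.5%, 13.4% and 12.2% of the shared peaks of each list. Chromosome 15 was also dense among the strongest decile, at 1.63, 1.50 and 1.20 times the autosomal median in replicates 1, 2 and 3, where chromosome 6 stood at 1.17, 1.25 and 0.51. Chromosomes 11 (1.52, 1.66 and 2.01) and 19 (1.51, 1.75 and 2.83) were dense there as well. Among regions in at least 2 replicates, chromosome 6 stood at 1.25 and chromosome 15 at 1.39 times the autosomal median, below chromosomes 11 (1.44) and 19 (1.56). With the stronger 50% of each list, the mean for chromosome 6 was 1.15 and for chromosome 15 was 1.37, below chromosomes 19 (1.44) and 11 (1.43).

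**Figure D4:**
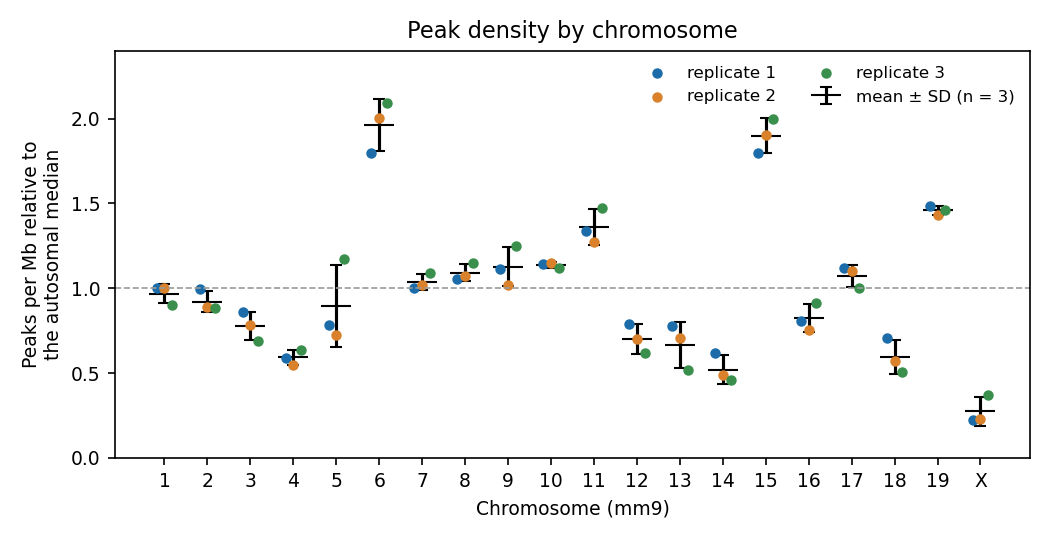
Peaks per Mb of each chromosome relative to the autosomal median of the same list (vertical axis) for the autosomes and chromosome X (horizontal axis). Coloured points are the 3 ChIP replicates and black marks the mean with SD (n = 3); chromosomes 6 and 15 lie highest and chromosome X lowest.

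Chromosome Y did not follow list length. It carried 55, 48 and 50 peaks in replicates 1, 2 and 3, which was 0.237%, 0.398% and 3.35% of each list. Its peak density was 2.33, 3.80 and 34.6 times the autosomal median, above every autosome in each list. This density rests on only 2.56 Mb between its first and last peak. The mean was 13.6 with all peaks and 5.10 with the stronger 50% of each list, and no chromosome Y peak was in the strongest decile of any list. Of its 64 regions, 35 were present in all 3 lists. A stretch of 123 kb at positions 2779685 to 2902393 held 32 regions, 28 of them in all 3 lists. None of these sites was strong: the best mean percentile rank on chromosome Y was 68.7, and no chromosome Y peak scored above 26.1 in replicate 1. The widest region common to all lists was on chromosome 17 at 39979964 to 39985741 (5778 bp), followed by regions of 4735, 4626 and 4042 bp on chromosome Y and 1 on chromosome 9 at 3000020 to 3003393 (3374 bp).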

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

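The excess of shared regions over random placement held under every alternative run, from 29.8-fold with placement within 50 kb of each peak to 432-fold with 1492 peaks per list, and from 89.6-fold to 193-fold when a replicate was left out. Shorter lists overlap less at random: the random median was 3 regions with 1492 peaks per list and 6 without replicate 1. The larger folds thus do not mark a stronger excess. The number of regions in at least 2 replicates depended on replicates 1 and 2: it ranged from 1160 to 7972 when a replicate was left out, and was 1297 with 1492 peaks per list, since fewer peaks entered. Without chromosome Y it was 7983 and without chromosomes 6 and 15 it was 6945. Requiring overlap of 50% of both lengths gave shares of 59.5% for replicate 2 in replicate 1, 61.1% for replicate 3 in replicate 1 and 63.3% for replicate 3 in replicate 2; no random placement was run for these. In the same order the shares were 91.3%, 98.8% and 98.1% with the stronger 50% of each list and 77.2%, 57.0% and 55.7% with 1492 peaks per list. Spearman's rho with the stronger 50% of each list was 0.75 for replicates 1 and 2, 0.69 for replicates 1 and 3 and 0.71 for replicates 2 and 3. With 1492 peaks per list it was 0.76, 0.70 and 0.68; the cause was not tested. The share of the strongest decile of replicate 1 met in replicate 3 was 31.7% with overlap of 50% of both lengths and 100% with 1492 peaks per list, where that decile holds fewer and stronger peaks. Chromosomes 6 and 15 no longer had the highest density among autosomes with the stronger 50% of each list. With 1492 per list, which leaves replicate 3 and its weak peaks whole, chromosome 6 (1.49) lay below chromosomes 11 and 19 (1.54 each). Chromosome 15 (1.66, with 2.00 in replicate 3) lay above. The mean density of chromosome Y was 13.6 with all peaks, 5.10 with the stronger 50% and 10.7 without the widest 1%. With 1492 per list it was 11.5, from replicate 3 alone. Leaving out a replicate gave 3.06 to 19.2, lowest without replicate 3. The 10 named regions stayed in all 3 lists with the stronger 50%, with 1492 peaks per list (lowest mean percentile rank 98.99) and with overlap of 50% of both lengths. Without the widest 1% of peaks, which takes out strong peaks too, 5 stayed in all 3 lists, 3 in 2 lists and 2 in 1 list. Alternatives fixed in advance for start-site distance, gene lists and motifs were not run, as no such result was made. No paired analysis was possible because the 3 input libraries have no values of their own here. What read depth limits cannot be quantified without read totals.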

Other observations

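The tests in this part were chosen after the result was seen, except the comparison of chromosomes 6 and 15 at matched score, whose prediction was written first, and the overlap of replicate 3 with replicate 1, a comparison fixed in advance that was turned to the question of a mixed-up sample afterwards. Regions in at least 2 replicates gathered along the genome. Of the 8025 regions, 1257 (15.7%) had another within 10 kb, against a median of 530 (6.60%) in 200 random placements, 2.37-fold higher (one-sided permutation p = 0.005, the smallest these placements can give). Without chromosome Y the share was 15.3%, and no other dense stretch was taken out. These placements spread regions evenly along each chromosome and leave out mappability and open chromatin. The excess thus shows only that the regions were unevenly spread, and no placement within 50 kb was run for it. Some dense 100 kb windows, though not those with the most regions, held at least 1 strong site. One on chromosome 6 at 87800001 to 87900000 (mm9) held 7 regions, 6 of them in all 3 lists, with a best mean percentile rank of 97.4. One on chromosome 5 at 136400001 to 136500000 held 5 regions, all 5 in every list, with a best mean percentile rank of 90.0. Windows on chromosome 3 at 107800001 to 107900000 and at 95000001 to 95100000 held 6 regions each, 2 and 1 of them in all 3 lists, with best ranks of 96.7 and 97.2. A window on chromosome 8 at 113300001 to 113400000 held 6 regions, 0 in all 3 lists, with a best rank of 94.0. The windows with the most regions had lower best ranks. Chromosome Y at 2800001 to 2900000 held 22 (20 in all 3 lists, best rank 68.7). Chromosome 11 at 3000001 to 3100000 held 22 (5 in all 3 lists, 82.1). Chromosome 9 at 3000001 to 3100000 held 13 (11 in all 3 lists, 84.1). Chromosome 8 at 19900001 to 20000000 held 12 (3 in all 3 lists, 64.6). Another window of low rank, on chromosome X at 120700001 to 120800000, held 7 (1 in all 3 lists, 41.0). Further chromosome X windows began at 120100001, 121200001 and 121300001 and held 6 regions each. Their best ranks were 34.0, 36.6 and 56.1. Chromosome Y at 2700001 to 2800000 held 6 (6 in all 3 lists, 67.9). Chromosome 3 at 151700001 to 151800000 held 7 (1 in all 3 lists, 87.0).

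Chromosomes 6 and 15 carried a surplus of weak peaks in each list. A few clusters or 1 amplified segment are argued against, since 100% of their 22 whole 10 Mb bins lay above the median bin of the other autosomes in replicate 1 (lowest bin 120 peaks, median of the others 85.5). A raised background called as peaks at places that differ between libraries stays open. At matched score decile, weak replicate 1 peaks on these chromosomes were met less often in replicate 2 than those on other autosomes. The common odds ratio was 0.769 (interval 0.639 to 0.925), with 149 of 2607 against 791 of 8810 met before matching. This is the direction predicted for such a background. The comparison draws on the same overlaps as the shares of unshared peaks given above, so it is no separate support. Matching by decile also leaves differences of score within a decile. Taken alone, chromosome 6 gave 0.714 (0.565 to 0.903) and chromosome 15 gave 0.845 (0.646 to 1.11). These intervals overlap, and the difference between the chromosomes was not tested. For chromosome 15, which was dense among strong peaks too, more binding sites stay open beside a raised background. As a hypothesis, extra copies of both chromosomes in these immortalised cells may give such a background, which read coverage of the input libraries, not analysed here, would test.

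Chromosome Y peaks stayed in the shortest list although they were weak. In replicate 3, 39 of 55 chromosome Y peaks of replicate 1 were met, against 1146 of 23132 elsewhere. At matched score decile, the odds that a replicate 1 peak was met in replicate 2 were 23.2 times higher on chromosome Y than elsewhere. The 95% interval was 10.5 to 51.2 (38 of 55 against 7936 of 23132 before matching). Recurrence of these peaks in replicate 2 was thus higher than at matched score elsewhere. No matched comparison was made for replicate 3, the shortest list. The matched comparison in replicate 2 is no separate test against ordinary sites whose detection follows their score. Chromosome Y was picked out with 35 of its regions in all 3 lists, each met in replicate 2. The interval also takes peaks as independent, though 31 of the 55 lay in a stretch of 123 kb. Reads piling up over repeated sequence are a candidate explanation that went with its test, since 47 of 55 chromosome Y peaks were wider than the median peak of their score decile elsewhere (median log2 width ratio 0.72, SD 1.00). The sequence and the coverage of the input libraries were not analysed here, so dense binding stays open as well.

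Replicate 3 had the shortest list. A mixed-up sample with other sites is argued against, since 80.1% of its peaks (95% interval 78.0 to 82.1%) overlapped a replicate 1 peak. Random placement gave 0.737%, and 3.18% when kept within 50 kb of each peak. A lower sensitivity of this library at the same sites stays open: 0% of its strongest decile (0 of 150 peaks, exact 95% interval up to 2.43%) was absent from both other lists, but this held for replicate 2 as well (0 of 1215 peaks), so the test does not set replicate 3 apart, and 283 of the 1492 peaks of replicate 3 were found in it alone. Fewer reads, a less efficient immunoprecipitation and a lower level of Nrf1 on chromatin in that sampling may each give a short list and stay open, since none was measured in the lists.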
